A study of Mus musculus with 25 samples.

How the data were processed

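RNA from mouse oocytes and embryos was sequenced in 25 libraries: MII oocytes (3 wild-type, WT, and 2 Smarca4 knockout, KO), PN3 zygotes (4 WT and 4 KO), early 2-cell embryos (E2C, 3 WT and 3 KO) and late 2-cell embryos (L2C, 3 WT and 3 KO). Per the labels' protocols, the oocytes came from superovulated females that were either B6D2F1 hybrids or C57BL/6 animals with floxed Smarca4 alleles and an oocyte Cre driver (Gdf9-Cre), and were used for injection of sperm. The strain of the female behind each library is not given in the sources used here, so a strain difference and the genotype cannot be told apart. Total RNA was depleted of ribosomal RNA, made into stranded libraries and read in pairs, per the labels' protocols. A sentence on the number of blastomeres in those protocols belongs to a chromatin assay and was not applied to these libraries.

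The deposited files hold 1 FPKM value per gene symbol and library (fragments scaled to transcript length and to the library's total), for 24412 symbols, as made by the authors. The submitters' processing notes name Trim Galore 0.4.5, HISAT2, StringTie and HTSeq and the builds mm10 and GRCm38, with no role or order, so which tool made the FPKM values, and whether strand was used, is not given in the sources used here. FPKM values carry no read counts. The depth of each library is therefore unknown, and no counting error could be given. The values are also relative to the other genes of a library, so a change in total RNA cannot be seen. Rises and falls between stages or genotypes are relative in this sense. The sum of FPKM was between 216308 (WT E2C replicate 2) and 252440 (WT MII replicate 1) per library. Genes above 0 numbered 9345 in WT E2C replicate 2 and 13585 to 16698 in the other 24 libraries. In WT E2C replicate 2, 69 genes were listed at 0 that exceeded an FPKM of 5 in the other WT E2C libraries.

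Libraries were rescaled by the median ratio to the geometric mean over 6492 genes with an FPKM of at least 1 in every library, and values were taken as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 3 of the 25 libraries were tested, which left 12079. A linear model with 1 mean for each stage and genotype (8 group means over 25 libraries, 17 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean and a robust prior. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and a gene was called at an adjusted p under 0.05. All libraries were put in 1 fit because the MII KO group has 2 libraries. Differences in the KO effect between successive stages were tested as interaction terms of the same fit. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. Figures were drawn with matplotlib 3.10.9.

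The fit was tested on simulated data in which 200 of 11863 genes were changed, over 5 simulations of independent normal noise with each stage's own spread. The median SD within a group was 0.08 (log2) at MII, 0.13 at PN3, 0.35 at E2C and 0.32 at L2C. With the spread shared by all 25 libraries, false calls made up 0.439% of calls at MII, 1.12% at PN3, 71.2% at E2C and 63.1% at L2C. Of genes changed 2-fold, 82.2%, 95.0%, 89.6% and 88.0% were recovered in the same order. With each stage fitted alone, false calls made up 4.09%, 3.97%, 4.17% and 3.34%, and 92.8%, 98.4%, 36.2% and 36.0% of genes changed 2-fold were recovered. The shares of false calls depend on the 200 genes changed and are not rates for the real calls. The planned fit was kept, and the counts with each stage fitted alone are given beside its counts.

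Gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a stage, and again with an estimated correlation. The 24 lists were BAF subunits, other chromatin remodelers, 2-cell genes, Obox genes, oocyte and maternal effect genes, mRNA clearance factors, ribosome biogenesis, cytosolic ribosomal proteins, proteasome, spliceosome, Pol II machinery, nuclear-encoded OXPHOS, mitochondria-encoded genes, replication-dependent histones, pluripotency, trophectoderm and primitive endoderm, p53 targets, unfolded protein and integrated stress, heat shock, cell cycle, DNA methylation and histone modification, cumulus and granulosa markers, sperm and testis markers, and blood and immune markers. The mitochondria-encoded list had 0 members among the genes tested. A further 3 lists were defined from the mean of both genotypes, so they were chosen on these samples: zygotic activation genes (called higher at L2C than at E2C, by a log2 difference of at least 2), early activated genes (called higher at E2C than at PN3, by at least 1) and maternally cleared genes (called lower at L2C than at MII, by at least 2).

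The test, the lists, the grouping and the rule for named genes were fixed before the data were examined. The rule named Smarca4, Smarca2 and the watch genes Dux, Zscan4d, Zfp352, Obox3, Nr5a2, Klf5, Klf17, Pou5f1, Sox2, Tfap2c, Dppa2, Zp3, Gdf9 and Btg4 at every stage; per stage, the 10 genes with the largest change in each direction among called genes with a mean of at least 5 in the higher group and KO libraries all above or all below all WT libraries, passing over names made of Gm plus digits, ending in Rik, holding -ps or bare identifiers; for each list, up to 2 called members at each end; and up to 5 genes in each direction for each interaction. Nanog, Cdx2 and Duxf3 were not among the genes tested. 1 gene that the rule names is not reported here. Coordinates are from the GENCODE annotation of GRCm38, in which 11631 of the 12079 symbols tested had a position. Overlaps of called genes were tested with Fisher's exact test, one-sided, and those of lower genes were recomputed without Smarca4, the deleted gene, after the results were seen.

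The alternatives were FPKM as deposited, rescaling to TPM, a pseudocount of 0.1, no filter, a filter at an FPKM of 5, library weights, the replicate number as a block, each stage or pair of stages fitted alone, an estimated correlation for camera, and leaving out each library in turn. Further alternatives were chosen after seeing the data and are named as such. No library was left out of the results. No pair of libraries held identical values, and Spearman's correlation across genes within a group was between 0.879 and 0.997.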

Results

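Expression was measured in 25 libraries from MII oocytes, PN3 zygotes (fertilised eggs with pronuclei), early 2-cell embryos (E2C) and late 2-cell embryos (L2C), with the ATPase of the BAF chromatin remodelling complex, Smarca4 (Brg1), either intact or deleted in the oocyte. The comparison of knockout (KO) with wild type (WT) at each stage asks how the loss of maternal Smarca4 changes the RNA of the oocyte and of the embryo around the start of its own transcription. There were 3 WT and 2 KO libraries at MII, 4 and 4 at PN3, 3 and 3 at E2C and 3 and 3 at L2C. Values are scaled FPKM, mean ± SD over the libraries of a group, and the read depth behind them is unknown. No label says whether replicates came from separate females, so the p-values measure only the spread between these samples, which may be technical.

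Smarca4 (chromosome 9, 21616169 to 21704230, GRCm38) separated the genotypes in every library. At MII it was 28.0 ± 2.31 in WT (n = 3) and 0.220 ± 0.00136 in KO (n = 2), and at PN3 31.1 ± 1.49 against 0.315 ± 0.0997 (n = 4 each). At E2C the KO level was 2.57 ± 2.27 against 28.4 ± 8.37, and at L2C 22.0 ± 0.807 against 71.0 ± 21.1 (n = 3 each). The log2 differences were -4.57, -4.61, -3.19 and -1.60, with limma adjusted p of 2.69e-08, 1.30e-10, 3.10e-06 and 0.00337. Within the KO libraries Smarca4 rose from PN3 to E2C by 1.25 (limma adjusted p = 0.00143) and from E2C to L2C by 2.88 (adjusted p = 3.00e-08). These p-values use the spread shared by all stages. The KO libraries at E2C stood at 1.82, 0.767 and 5.12, each above every KO library at PN3, and the size of the first rise leaned on replicate 3. Smarca2, the paralog of Smarca4 and the other ATPase of the complex, was not called at any stage. At L2C Smarca2 stood at 37.8 ± 3.91 in KO and 29.0 ± 6.86 in WT (limma adjusted p = 0.0914).

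**Figure D1:**
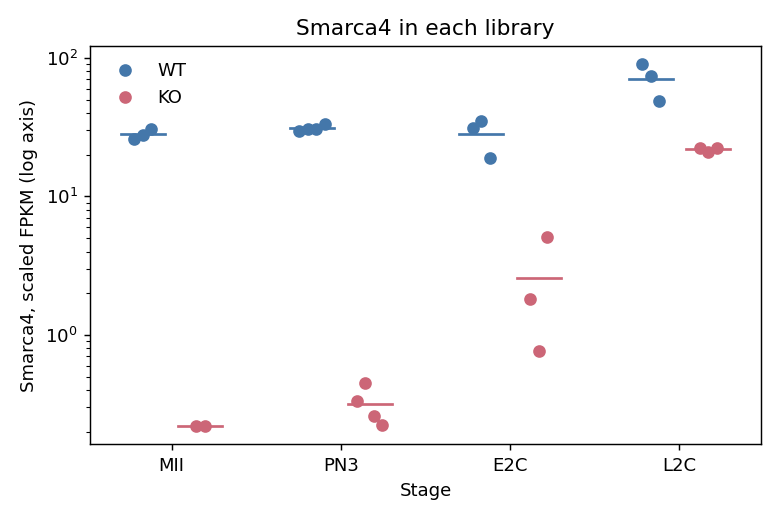
Smarca4 in scaled FPKM (log axis) in each library by stage, with WT in blue, KO in red and a line at each group mean. KO means were 0.220 at MII, 0.315 at PN3, 2.57 at E2C and 22.0 at L2C, below every WT library of the same stage.

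The WT libraries were first compared between successive stages. From MII to PN3, 342 genes rose and 1000 fell (limma), and the total of 1342 became 790, 824 and 842 without WT_MII replicates 2, 1 and 3. Among those that fell were the oocyte genes Zp3, a zona pellucida protein, by 2.34 (log2), and Gdf9, an oocyte growth factor, by 1.94. The transcription factor Dux, which precedes the 2-cell programme, rose by 2.35. From PN3 to E2C, 2145 genes rose and 2797 fell. Of 46 measured 2-cell genes 40 rose and 2 fell, with a median of 3.60, among them Zscan4d (3.93) and Zfp352 (4.52), and 51 of 64 replication-dependent histone genes rose. From E2C to L2C, 4962 genes rose and 2938 fell. Of 85 cytosolic ribosomal protein genes 81 rose, of 92 ribosome biogenesis genes 79 rose and 3 fell, and 42 of 57 oocyte and maternal effect genes fell and 2 rose. Klf5, a transcription factor of the preimplantation embryo, rose by 3.78, while Dux fell by 3.03 and Zscan4d fell by 2.06. The fall of Zscan4d came from WT_L2C replicates 1 and 2 (4.32 and 4.73), since replicate 3 stood at 33.4. With FPKM as deposited the split from PN3 to E2C was 1311 higher and 3794 lower, and with TPM the split from MII to PN3 was 408 and 703.

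In MII oocytes Smarca4 was the only gene called between KO and WT, with 0 higher and 1 lower among 12079 genes tested by limma. At an unadjusted p under 0.05, 226 genes differed. Genes whose KO libraries all lay above or all below the WT libraries made up 40.4% of all genes, where chance gives 20.0%. No fixed gene list was called at MII: the lowest adjusted p by camera was 0.115, for the mRNA clearance factors (37 measured, median difference 0.05). This depended on the libraries: the mRNA clearance factors were called higher without WT_MII replicate 1 (adjusted p = 0.0216), and the oocyte and ribosomal protein lists without KO_MII replicate 1 (0.00600 each), where the lone KO library is assumed to vary like the other groups. With MII and PN3 fitted together, chosen after the results were seen, the Obox genes were called lower at MII by camera (median -0.25, 1 member called, adjusted p = 0.00204). That fit was not run with an estimated correlation. In the main fit the camera adjusted p of the Obox genes was 0.126, and 0.944 with an estimated correlation. The count of 1 called gene rested on the shared estimate of spread. With MII fitted alone, 176 genes were higher and 248 lower.

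In PN3 zygotes 4 genes were higher and 6 lower in KO by limma, all with KO and WT libraries apart (n = 4 each). The histone gene Hist2h2aa2 was 28.3 ± 25.5 in KO and 1.61 ± 0.726 in WT, a log2 difference of 3.18 ± 0.59 (SE) with an adjusted p of 0.0341. Reads of histone genes can be shared between near-identical copies, so this value is uncertain. Zmynd11, a reader of methylated histone H3, was 12.0 ± 1.62 against 7.05 ± 1.35 (0.70, adjusted p = 0.0350). Sh2d3c, a signalling adaptor, was 5.08 ± 0.536 against 14.7 ± 3.02 (-1.35, adjusted p = 1.33e-04), and Dip2c was 2.86 ± 0.234 against 6.00 ± 0.526 (-0.86, adjusted p = 0.00532). At an unadjusted p under 0.05, limma gave 333 genes. With PN3 fitted alone 48 genes were higher and 46 lower. The total of 10 became 6 without WT_PN3 replicate 2, without WT_PN3 replicate 3 and without KO_PN3 replicate 2.

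Nuclear-encoded OXPHOS genes, which build the respiratory chain, were the only fixed list called at PN3. Their median difference was 0.11 over 77 genes, with 0 members called over all genes and 0 adjusted over the list alone. Leaving out single libraries moved this median between 0.05 (without WT_PN3 replicate 2) and 0.16 (without WT_PN3 replicate 4). The camera adjusted p was 0.0421, and the adjusted p = 0.952 with an estimated correlation. The call was lost with TPM (0.0583), without WT_PN3 replicate 2 (0.392) and also without WT_PN3 replicate 1 (0.169), KO_PN3 replicate 3 (0.173) and KO_PN3 replicate 4 (0.292). Replication-dependent histones missed the threshold (median -0.08, adjusted p = 0.0571) and were called lower without WT_PN3 replicate 1 (0.00715) or 2 (7.74e-08) and without KO_PN3 replicate 3 (0.00237) or 4 (7.51e-08). The oocyte list was called higher without KO_PN3 replicate 2 (0.0491).

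When MII and PN3 were each fitted alone, 18 genes differed in the same direction at both stages and 0 in opposite directions. Higher at both were 8 genes, where 0.699 were expected from independent lists (Fisher's exact test, one-sided, p = 3.98e-07), and lower at both were 9 besides the deleted Smarca4, where 0.920 were expected (p = 2.52e-07). The lower genes included Wwc1, an upstream component of the Hippo pathway, at -1.13 in MII and -0.94 in PN3, and Dip2c at -0.82 and -0.86. Gm8817, a long noncoding RNA gene on the X chromosome, was at -1.67 and -1.72. The higher genes included Mfhas1 (1.11 and 1.36) and Aldh1a2, which makes retinoic acid (0.71 and 0.81). With MII and PN3 fitted together, 53 genes were called at both stages, 51 in the same direction and 2 in opposite directions, Anxa5 (-1.75 and 0.48) and Midn (0.34 and -0.25). These genes were named after their values were seen, because both fits are alternatives. Of the 18 genes, 11, the deleted Smarca4 among them, kept the sign of their difference at all 4 stages. Since they were chosen for 1 sign at MII and PN3, only the signs at E2C and L2C bear on this, and some would match by chance.

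**Figure D2:**
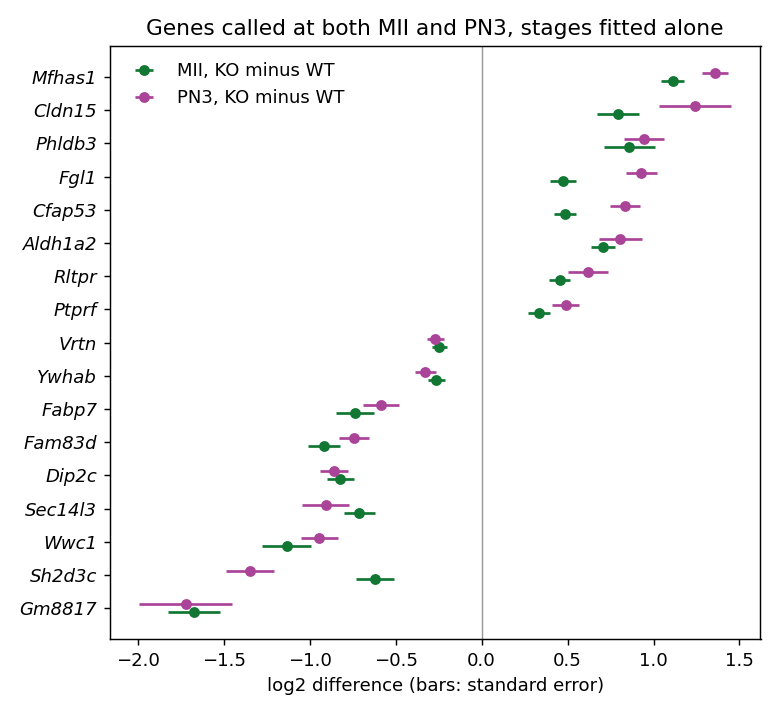
Log2 difference between KO and WT (horizontal axis, bars show the standard error) at MII and PN3 for the genes called at both stages with each stage fitted alone, without Smarca4. Every gene lies on the same side of 0 at both stages, from Gm8817 (-1.72 at PN3) to Mfhas1 (1.36 at PN3).

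The spread between libraries was several times larger at the 2-cell stages. In simulated data the fit of all 25 libraries gave false calls at a rate of 71.2% of calls at E2C and 63.1% at L2C, so single genes called at these stages are given as candidates. These shares depend on the 200 genes changed in the simulation and are not rates for the real calls. The simulated fit called a mean of 654.6 genes at E2C and 507.6 at L2C, against 212 and 1873 in the data. With each stage fitted alone limma called 0 genes at E2C and 0 at L2C, while recovering 36.2% and 36% of genes changed 2-fold in the simulation and 83.2% and 85.4% of genes changed 4-fold. The deleted Smarca4 was thus missed too (log2 differences of -3.19 and -1.60), so the 0 calls do not show that changes are absent. The recovery also depends on the 200 genes changed and on independent noise.

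**Figure D3:**
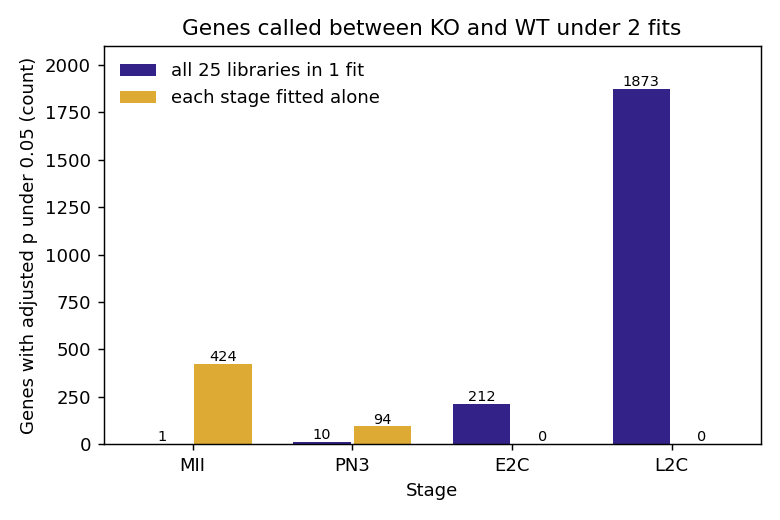
Number of genes called between KO and WT (vertical axis, adjusted p under 0.05) at each stage with all 25 libraries in 1 fit and with each stage fitted alone. The counts were 1, 10, 212 and 1873 from MII to L2C in the shared fit, and 424, 94, 0 and 0 with each stage alone.

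In early 2-cell embryos genes of the 2-cell programme had a lower median in KO, called by camera only at the preset correlation. Of 46 measured 2-cell genes 0 were higher and 8 lower over all genes tested, and 0 and 20 adjusted over the list alone, with a median difference of -0.73. Tmem92 was 6.19 ± 2.12 in KO and 22.9 ± 4.72 in WT (n = 3 each, -1.76 ± 0.35 SE, limma adjusted p = 0.0136), and Zscan4c, of a family active in 2-cell embryos, 8.96 ± 7.14 against 26.0 ± 7.11 (-1.65, adjusted p = 0.0493). Zscan4a (-1.61) and Zscan4b (-1.59) were also called and Zscan4d was not (17.8 ± 13.1 against 42.0 ± 9.87, adjusted p = 0.125). Reads can be shared between these near-identical copies. Dux, which switches on this family, was 12.5 ± 2.67 in KO and 13.9 ± 3.49 in WT (adjusted p = 0.822). The list was called lower by camera (adjusted p = 3.40e-17; adjusted p = 0.594 with an estimated correlation). Its 8 lower genes became 1 without KO_E2C replicate 2, 3 without KO_E2C replicate 1, 14 without KO_E2C replicate 3 and 5 with TPM.

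Replication-dependent histones were the other fixed list called at E2C. Of 64 genes 0 were higher and 4 lower, with 0 and 8 adjusted over the list alone, and the median was -0.35. Hist1h2ak was 4.39 ± 1.89 in KO and 16.5 ± 14.7 in WT (-1.46), and Hist1h2ag 24.4 ± 4.99 against 54.9 ± 25.0 (-1.05), both subject to shared reads. The camera adjusted p was 6.38e-09, and the adjusted p = 0.679 with an estimated correlation. The 4 lower histones became 0 without KO_E2C replicate 2, 1 without KO_E2C replicate 1, KO_E2C replicate 3 or WT_E2C replicate 1, 14 without WT_E2C replicate 3 and 1 with TPM. The 433 early activated genes, which rose from PN3 to E2C, had a median of -0.52, a fold of 0.695, with 2 higher and 55 lower, or 3 and 127 adjusted over the list alone. Their camera p was 9.00e-31 and 1.83e-04 with an estimated correlation. The 55 lower genes ranged from 17 without KO_E2C replicate 2 to 139 without WT_E2C replicate 3. This list was chosen on these samples and is not independent evidence of its direction, and it shares 37 genes with the 2-cell list and 30 with the histones.

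The 662 maternally cleared genes, which fell at least 4-fold from MII to L2C, were higher in KO at E2C with a median of 0.27. Of them 24 were higher and 0 lower, or 65 and 2 adjusted over the list alone (camera p = 9.27e-10, and p = 0.0592 with an estimated correlation). The 24 ranged from 5 without KO_E2C replicate 2 to 132 without WT_E2C replicate 3, and became 8 without a filter, 0 with library weights, 38 as deposited and 41 with TPM. This list too was chosen on these samples and is not independent evidence of its direction, and it was read at E2C after its value there was seen. Its mean was 3.36, 3.16 and 3.54 in WT and 3.51, 3.65 and 3.79 in KO.

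For the early activated, 2-cell and histone lists KO_E2C replicate 3 lay nearer to the WT libraries than the other KO libraries did. The early activated genes averaged 2.76, 2.75 and 3.26 (log2) in KO replicates 1 to 3 and 3.53, 3.38 and 3.34 in WT, the 2-cell genes 2.74, 2.86 and 3.52 against 3.62, 3.69 and 4.21, and the histones 3.83, 3.83 and 4.14 against 4.35, 4.37 and 4.22. Zscan4d was 11.7, 8.82 and 32.7 against 32.7, 41.1 and 52.4. Smarca4 itself was 1.82, 0.767 and 5.12 against 31.4, 34.9 and 19.0, so it too was nearest to WT in KO replicate 3. The ribosomal RNA precursor Rn45s was highest in both replicates 3, at 812, 1029 and 10915 in KO and 2595, 2208 and 7357 in WT. Without KO_E2C replicate 3 the early activated median was -0.71, and with both replicates 3 left out, chosen after the results were seen, it was -0.79, with both fixed lists still called by camera (adjusted p = 5.61e-12 for 2-cell genes and 1.11e-09 for histones).

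Over all genes 100 were higher and 112 lower at E2C, and 2231 had an unadjusted p under 0.05. KO and WT libraries were apart for 193 of the 212 called genes and for 9.74% of all genes, where chance gives 10.0%. The largest increases included Dnajc15, a mitochondrial co-chaperone (6.32 ± 2.23 against 1.30 ± 1.54, log2 1.85), Psmb4, a proteasome subunit (5.29 ± 0.227 against 1.11 ± 1.23, 1.75), Tma16 (1.76), Taf1b, a factor of RNA polymerase I (1.52), Pradc1 (1.5), Rnf17, a Tudor protein of germ cells (1.48), Rltpr (1.43), Cage1 (1.36), Cttnbp2 (1.18) and Terf1, a telomere repeat binding protein (1.17). Besides Smarca4 and the genes named above, the largest decreases included Atp6v0a4, a proton pump subunit (-1.35), Zfp622 (-1.25), Polr1c, a subunit shared by RNA polymerases I and III (-1.16), and Chka, choline kinase (-1.15). Rescaling moved the balance of these calls: 153 higher and 81 lower with TPM, where the median of all genes was at 0.11, and 137 and 94 with FPKM as deposited. Single libraries moved the count as well, to 55 without KO_E2C replicate 2, 120 without WT_E2C replicate 2, 132 without KO_E2C replicate 1, 544 without WT_E2C replicate 1 and 1514 without WT_E2C replicate 3.

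Members of other lists were called singly at E2C. Higher in KO were the oocyte transcription factor Figla (1.67) and the translation regulator Cpeb1 (0.65), within 3 of 57 oocyte and maternal effect genes called. Psma1 (1.01) joined Psmb4 among 2 of 44 proteasome genes, and Med17 (0.89) and Taf6l (0.93) were among 3 of 101 Pol II genes. The maintenance methyltransferase Dnmt1 (0.52), the laminin chain Lamb1 (0.44), the disulfide isomerase Pdia3 (0.65) and the small heat shock protein Hspb1 (1.34) were also higher. Lower were cyclin E1, Ccne1 (-0.91), the NuRD subunit Mta2 (-0.85), the splicing genes Snrpa (-0.75) and Srsf7 (-0.74), Nol11 (-0.82) and Rpl9 (-0.88). Of 77 OXPHOS genes, Ndufc2 was higher (an FPKM of 1.91 ± 0.594 in KO, and listed at 0 in all 3 WT libraries) and Atp5g1 lower (-1.18). None of these lists was called by camera at E2C with all libraries. The unfolded protein and integrated stress list was called lower without WT_E2C replicate 3 (adjusted p = 0.0183) and without KO_E2C replicate 3 (0.0124), and the ribosomal proteins without KO_E2C replicate 3 (0.0124).

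In late 2-cell embryos oocyte and maternal effect genes had a higher median in KO, called by camera only at the preset correlation. Of 57 genes 27 were higher and 0 lower over all genes, and 30 and 1 adjusted over the list alone, with a median of 0.44. Bcl2l10, an oocyte BCL2 family member, was 365 ± 76.3 in KO and 137 ± 128 in WT (n = 3 each, 1.78 ± 0.33 SE, limma adjusted p = 0.00370), and Rfpl4 was 339 ± 112 against 119 ± 94.2 (1.72). Btg4, an adaptor of maternal mRNA decay, was 1507 ± 358 against 715 ± 370 (1.16). The oocyte list was called by camera (adjusted p = 1.24e-11; adjusted p = 0.285 with an estimated correlation). Its 27 higher genes became 4 without WT_L2C replicate 1, 7 without WT_L2C replicate 2, 14 and 12 without KO_L2C replicates 2 and 3, and 36 without WT_L2C replicate 3. Its mean was 4.50, 4.68 and 5.40 in WT replicates 1 to 3 and 5.30, 5.52 and 5.57 in KO, so WT replicate 3 lay above KO replicate 1. Obox homeobox genes were higher too, with 4 of 6 called, a median of 1.31 and examples Obox5 (1.77) and Obox7 (1.59), whose copies can share reads (adjusted p = 0.00197; adjusted p = 0.285 with an estimated correlation). Of the 46 2-cell genes 6 were higher and 0 lower, or 10 and 2 adjusted over the list alone, with a median of 0.43, Gm6763 at 2.99 and Tcstv1 at 1.62 (adjusted p = 0.00164; adjusted p = 0.695 with an estimated correlation). The last call was lost without WT_L2C replicate 1 (adjusted p = 0.109, median 0.19, 0 called) and without WT_L2C replicate 2 (0.0621, median 0.20, 0 called), while without WT_L2C replicate 3 the median was 0.96 with 26 higher and 2 lower.

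Genes of ribosome production had lower medians in KO at L2C, and camera called their lists only at the preset correlation. Of 92 ribosome biogenesis genes 0 were higher and 32 lower, or 0 and 54 adjusted over the list alone, with a median of -0.56. Wdr74 was 12.1 ± 0.606 in KO and 35.8 ± 21.9 in WT (-1.29) and Gnl3l 4.00 ± 0.769 against 11.7 ± 6.04 (-1.21). Of 85 cytosolic ribosomal protein genes 16 were lower and 0 higher, or 21 and 1 adjusted over the list alone, with a median of -0.60 and Rpl13 at 54.9 ± 21.5 against 111 ± 46 (-0.97). The adjusted p by camera was 5.21e-14 for ribosome biogenesis and 6.60e-09 for ribosomal proteins, and the adjusted p = 0.285 and adjusted p = 0.431 with an estimated correlation. The spliceosome list was lower with a median of -0.35, with 1 of 73 higher (Prpf39, 0.77) and 14 lower, among them Lsm8 (-1.23) and Snrpd2 (-1.11), at an adjusted p of 3.97e-05 (adjusted p = 0.285 with an estimated correlation). Without WT_L2C replicates 1, 2 and 3 in turn, the lower genes were 3, 4 and 66 for ribosome biogenesis, 1, 1 and 42 for ribosomal proteins and 3, 5 and 34 for the spliceosome, and without KO_L2C replicates 2 and 3 they were 12 and 10, 1 and 3, and 5 and 7. The 3 lists stayed called by camera in each case.

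The proteasome list had a median of -0.28, with Psmd9 higher (0.66) and 6 of 44 lower, such as Psmc5 (-0.98) and Psmd13 (-0.98), at an adjusted p of 0.0119. The Pol II list had a median of -0.27, with 6 of 101 higher, among them Med30 (1.47) and Gtf2a2 (0.98), and 13 lower, among them Nelfe (-0.86) and Supt4a (-0.79), at an adjusted p of 0.0164. With an estimated correlation these became adjusted p = 0.582 and adjusted p = 0.431. Both calls were lost without WT_L2C replicate 1 (0.238 and 0.138). Without WT_L2C replicates 1, 2 and 3 in turn, the lower genes were 0, 0 and 20 for the proteasome and 0, 4 and 34 for Pol II, and the proteasome median ranged from -0.13 to -0.55.

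**Figure D4:**
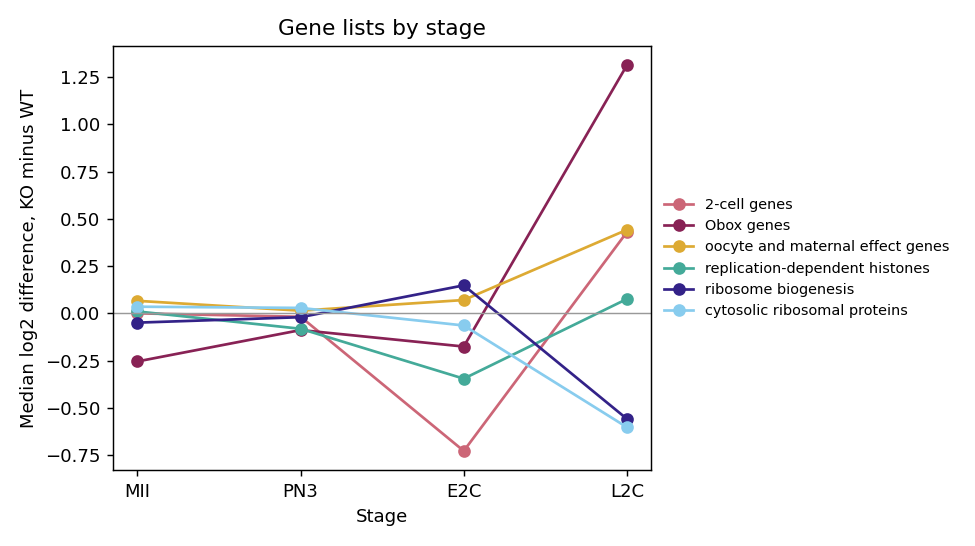
Median log2 difference between KO and WT (vertical axis) at each stage for 6 gene lists, with 1 line for each list. The 2-cell genes lie at -0.73 at E2C and 0.43 at L2C, and ribosome biogenesis lies at -0.56 at L2C.

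The 1073 zygotic activation genes, which rose at least 4-fold on the log2(FPKM + 1) scale from E2C to L2C, had a median difference of -0.55 at L2C, a fold of 0.683. Of them 2 were higher and 281 lower, or 2 and 407 adjusted over the list alone, and 92.6% lay below 0 (camera p = 1.70e-25, and p = 0.0307 with an estimated correlation). The 662 maternally cleared genes had a median of 0.28, close to that at E2C (0.27; the difference between the stages was not tested), with 136 higher and 8 lower, or 157 and 11 adjusted over the list alone (camera p = 5.56e-10, and p = 0.0562 with an estimated correlation). Both lists were chosen on these samples and are not independent evidence of their direction. Without WT_L2C replicates 1, 2 and 3 in turn, 28, 61 and 686 activation genes were lower and 41, 41 and 252 cleared genes higher, and without KO_L2C replicates 2 and 3 these were 102 and 117, and 76 and 66. The median of the cleared genes depended on the choice of list and of libraries: it was 0.06 with the list taken from KO libraries alone, 0.43 without WT_L2C replicate 3 and 0.17 with a term for genes detected. The L2C libraries also differed in genes detected: WT replicate 3 and KO replicates 2 and 3 had at least 16267 genes above 0, and the other 3 libraries at most 14407. Within the libraries with many genes the median was -0.23 for activation genes and 0.13 for cleared genes, and within those with few it was -0.61 and 0.20. For the 2-cell genes it was -0.23 with many and 0.72 with few, so their sign differed between the classes, as it did for the proteasome list. The oocyte list lay at 0.17 and 0.68, Obox genes at 0.46 and 1.44, ribosome biogenesis at -0.22 and -0.65, ribosomal proteins at -0.24 and -0.71, spliceosome at -0.11 and -0.36, Pol II at -0.09 and -0.32, and proteasome at 0.02 and -0.38.

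**Figure D5:**
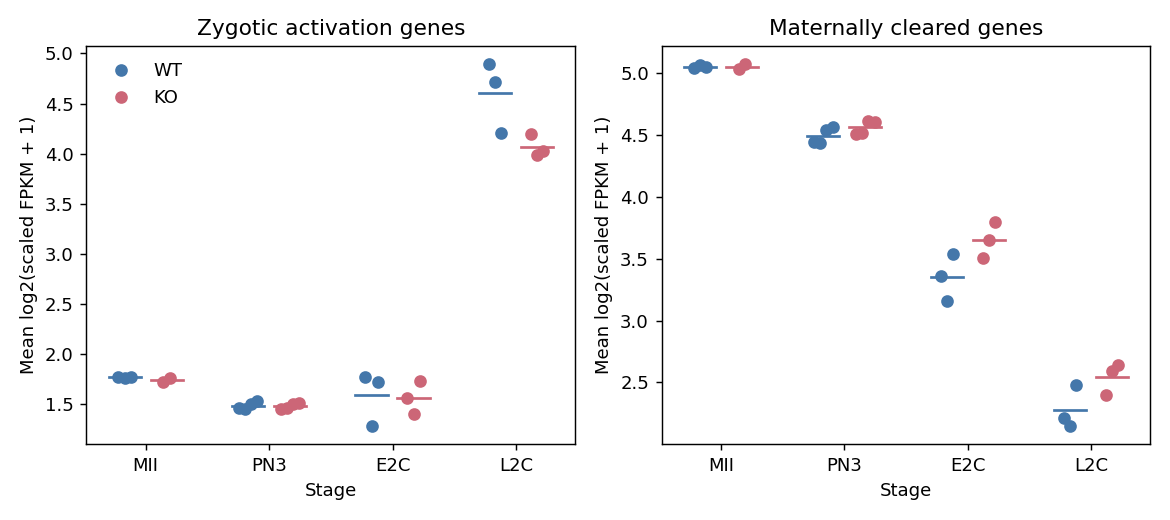
Mean log2(scaled FPKM + 1) of the zygotic activation genes and of the maternally cleared genes in each library by stage, with WT in blue, KO in red and a line at each group mean. At L2C the activation genes average 3.99 to 4.19 in KO and 4.21 to 4.89 in WT.

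Over all genes 934 were higher and 939 lower at L2C, with 3894 at an unadjusted p under 0.05. KO and WT libraries were apart for 1166 of the 1873 called genes and for 20.1% of all genes, where chance gives 10.0%. The largest increases included Trappc2, of vesicle transport (18.5 ± 2.94 against 5.76 ± 6.75, 2.05), Smco4 (1.86), Phlda2, an imprinted gene (1.74), Nefl, the neurofilament light chain (1.63), Gnpda2 (1.60), AU022751 (1.52), Agbl3 (1.51), the transcription factor Cebpa (1.49) and Mir877 (2.24), which lies inside Abcf1 and may hold its reads. The largest decreases included the erythroid factor Gata1 (10.2 ± 0.304 against 36.7 ± 24.7, -1.47), Emc4 (-1.61), Ppp1r16b (-1.61), Stmn3 (-1.61), Gpatch4 (-1.56), Smyd5 (-1.49), Apba3 (-1.48), the read-through Dpm1-adnp (-2.23) and Snord2 (-1.68), which lies inside Eif4a2. With TPM the split was 908 higher and 479 lower. The count was 346 without WT_L2C replicate 1, 430 without WT_L2C replicate 2, 869 without KO_L2C replicate 2, 872 without KO_L2C replicate 3 and 4274 without WT_L2C replicate 3.

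Transcription factors of the embryo were called in both directions at L2C. Nr5a2, a nuclear receptor, was 21.2 ± 6.10 in KO and 36 ± 8.04 in WT (-0.74, limma adjusted p = 0.0136), Dppa2 49.9 ± 3.55 against 94.6 ± 23.2 (-0.88), and Tfap2c 18.6 ± 5.14 against 31.9 ± 11.4 (-0.71). Pou5f1 was 167 ± 15.1 against 117 ± 44 (0.57) and Sox2 3.91 ± 0.0814 against 1.56 ± 0.481 (0.96), both of the pluripotency network. Klf5, Klf17, Obox3, Zfp352, Zscan4d, Dux, Zp3 and Gdf9 were not called at L2C. Of 28 pluripotency genes 5 were higher, with Tcl1 at 1.48, and 7 lower, with Fgf4 at -0.85. Of 20 trophectoderm and primitive endoderm genes 1 was higher (Dab2, 0.74) and 3 lower, among them Gata4 (-0.74) and Tead4 (-0.85).

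The other lists were not called by camera at L2C with all libraries. DNA methylation and histone modification was called lower without KO_L2C replicate 1 (adjusted p = 0.0393) and histones higher without KO_L2C replicate 2 (0.0319). Of 26 BAF subunits 2 were higher, Ss18l1 (0.60) and Ss18 (0.37), and 6 lower, 5 of them besides the deleted Smarca4, among them Brd9 (-1.12), and of 27 other chromatin remodelers 2 were higher, Chd1l (0.62) and Chd5 (0.50), and 6 lower, among them Baz2a (-0.75) and Ino80 (-0.72). Of 60 genes of DNA methylation and histone modification 5 were higher, with Zfp57 (0.87) and Uhrf1 (0.72), and 10 lower, with Prmt1 (-0.99) and Ehmt2 (-0.99). The mRNA clearance factors had 7 of 37 higher, with Pan2 at 0.93, and 2 lower, Ythdf2 (-0.56), a reader of methylated RNA, and Tead4 (-0.85), a transcription factor that is also in the trophectoderm list. Heat shock genes had 5 of 21 higher, with Hspa2 (1.66) and Hspe1 (0.78), and 4 lower, with Fkbp4 (-0.76) and Hsph1 (-0.68). Cell cycle genes had 6 of 62 higher, with Wee2 (1.09) and Aurkc (0.98), and 2 lower, Incenp (-0.72) and Cdt1 (-0.44). Of 28 p53 targets 6 were lower, with Sesn2 (-0.93) and Bax (-0.93), and of 35 unfolded protein and integrated stress genes 4 were lower, with Phgdh (-1.26) and Psat1 (-0.96). OXPHOS genes had 2 of 77 higher, Ndufs6 (1.39) and Ndufc2 (1.26), and 3 lower, among them Atp5k (-1.10) and Uqcrc1 (-0.87). Histones had Hist1h2aa higher (0.55). Of 7 cumulus and granulosa markers Cyp19a1 was higher (0.84) and Gja1 (-1.20) and Nr5a2 lower. The 5 sperm and testis markers and the 4 blood and immune markers had 0 called at any stage by limma.

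The KO effect was compared between successive stages. From E2C to L2C it differed for 771 genes, 322 of them more positive at L2C and 449 more negative (3195 at an unadjusted p under 0.05). The largest shifts upwards were in BB287469 (2.74), Tmem92 (2.55), Trappc2 (2.54), Zscan4d (2.42) and Mir877 (2.24), and downwards in Rpl24 (-2.78), Snord42b (-2.78), which lies inside Rpl23a, Psmb4 (-2.56), AF357359 (-2.54) and Dnajc15 (-2.50). For Zscan4d the shift leaned on WT_L2C replicates 1 and 2 (4.32 and 4.73), with replicate 3 at 33.4. The 2-cell genes shifted upwards by a median of 1.35 (12 called upwards, 0 downwards; camera adjusted p = 1.21e-14, adjusted p = 0.436 with an estimated correlation). From MII to PN3 and from PN3 to E2C limma called 0 genes, with 113 and 1039 at an unadjusted p under 0.05. With the libraries of the 2 stages alone the counts were 14, 1 and 0 from the first step to the last. From PN3 to E2C the count became 261 without WT_E2C replicate 3, 12 without WT_E2C replicate 1, 5 without KO_E2C replicate 3, 4 without WT_E2C replicate 2, 2 without KO_E2C replicate 1 or 2 and 1 without KO_PN3 replicate 1. The count from E2C to L2C ranged from 94 without WT_L2C replicate 2 to 3180 without WT_L2C replicate 3, with 100 without WT_L2C replicate 1, 159 and 191 without KO_L2C replicates 2 and 3, 360 and 415 without KO_E2C replicates 2 and 1, and 1505 and 1404 without WT_E2C replicates 1 and 3.

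Few genes were called at successive stages. Higher at both PN3 and E2C were Fgl1, Mfhas1 and Zmynd11 (Fisher's exact test, one-sided, unadjusted p = 2.19e-06; 0.0331 expected), and lower at both, besides the deleted Smarca4, was Dip2c (1 gene, unadjusted p = 0.0451). The test takes genes as independent, which these may not be. Fgl1 and Mfhas1 are both on chromosome 8 (from 41191434 and from 35587798). Zmynd11 (9684833 to 9765330) and Dip2c (9276528 to 9668928) lie close together on chromosome 13. Fgl1 and Mfhas1 fell outside the rule for named genes and were named after their values were seen. By the same exact test, 8 genes were higher at both E2C and L2C, where 7.73 were expected (p = 0.514), and 11 besides Smarca4 were lower at both, where 8.62 were expected (p = 0.243).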

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

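All tests of explanations here, with their criteria, were chosen after the results were seen, and the criteria for the region beside Smarca4 and for WT_E2C replicate 2 were set when their values were already known. The comparisons of KO effects between stages were planned as interaction terms. In the PN3 groups, 86 sets of 4 values (named genes and list means) were checked for a library far from the others and 0 stood out, where chance would give about 1 in 20.

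The KO effect differed between E2C and L2C for 14 named genes. It shifted by 2.74 (log2) for BB287469, 2.55 for Tmem92, 2.54 for Trappc2, 2.42 for Zscan4d, 2.24 for Mir877, 1.59 for Smarca4, 1.37 for Sox2 and 1.25 for Btg4. It shifted by -2.78 for Rpl24, -2.78 for Snord42b, -2.56 for Psmb4, -2.54 for AF357359, -2.50 for Dnajc15 and -1.38 for Dppa2. Among lists it shifted from E2C to L2C by a median of 1.45 for Obox genes, 1.35 for 2-cell genes, 0.52 for histones and 0.39 for oocyte and maternal effect genes, and by -0.69 for ribosome biogenesis, -0.62 for ribosomal proteins, -0.41 for proteasome, -0.25 for Pol II machinery and -0.25 for spliceosome. From PN3 to E2C it shifted by -0.72 for 2-cell genes, -0.27 for histones and -0.20 for the unfolded protein and integrated stress list. From MII to PN3 it shifted by 0.12 for OXPHOS genes, -0.072 for mRNA clearance factors and -0.064 for DNA methylation and histone modification. With an estimated correlation only the mRNA clearance factors from MII to PN3 stayed past the threshold (adjusted p = 0.0481).

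Regroupings of the libraries bear on these counts. They take the libraries as separate units, so a chance difference between the females behind the groups is not covered. For the difference from E2C to L2C, chance could not be excluded: 15 of 100 drawn regroupings gave at least the 771 genes of the real one, and the highest other gave 1913. For the difference from PN3 to E2C the regroupings cannot tell, because the real value was 0, which all 100 reach (highest 39). For genes called in the same direction at PN3 and E2C, 1 of 100 regroupings, the real one, was as large (5 genes, or 4 without the deleted Smarca4, highest other 0). This cannot decide whether the sharing exceeds chance. Other splits of PN3 called at most 2 genes, which left almost none to share. The shared genes may not be separate effects, since Fgl1 and Mfhas1 are on chromosome 8 and Zmynd11 and Dip2c on chromosome 13. For E2C and L2C chance could not be excluded, with 6 of 100 (20 genes, highest other 94).

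The 2-cell and early activated genes had lower medians in KO at E2C. Of 46 2-cell genes 0 were called higher and 8 lower, and of 433 early activated genes 2 higher and 55 lower. With an estimated correlation camera gave an adjusted p = 0.594 for the 2-cell list, so its call was lost. The early activated list, which was chosen on these samples, kept its call. The 2-cell median was -0.84 without WT_E2C replicate 2, but this does not weigh poor detection there, since genes lost in a WT library would make KO look higher. An earlier point of development of the KO libraries remains open: genes that fall from PN3 to E2C had a median of 0.41 in KO and the maternally cleared genes one of 0.27, but for the former KO libraries (2.62 to 3.04) and WT libraries (1.94 to 2.70) overlapped, and these cannot be told apart. The WT value of 1.94 was that of WT_E2C replicate 2, against 2.46 and 2.70, so poor detection there could itself raise the 0.41. With 10 splits of 6 libraries no share under 0.05 is possible. The real split gave 212 genes, 2 lists and medians of 0.525 for early activated and 0.267 for cleared genes in size, and 4, 7, 1 and 2 of the 10 splits gave as much, with 415 genes, 6 lists, 0.471 and 0.283 as the highest others.

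At L2C maternal genes had higher and activation genes lower medians in KO. With an estimated correlation camera gave an adjusted p = 0.285 for the oocyte list, p = 0.0562 for the cleared genes and p = 0.0307 for the activation genes. The values are relative, so a lower share of activation genes can by itself raise that of maternal genes. The changes need not be separate. An earlier point of development of the KO libraries is a candidate explanation: 92.4% of the 1626 called genes with a stage change from E2C to L2C differed against that change, compared with 76.6% of all tested genes with one. On a scale from the E2C mean (0) to the L2C mean (1) WT libraries lay at 1.21, 1.15 and 0.95 and KO libraries at 0.95, 0.87 and 0.88. This scale was built from 1192 genes, of which 1073 are the zygotic activation genes, so it largely restates their lower median. Neither the share of 92.4% nor the scale can tell a delay from lower activation at the same point of development. A difference between libraries with many and few genes detected cannot be told apart, because the activation median of -0.23 among libraries with many genes rests on a single WT library. With 10 splits no share under 0.05 is possible: the real values were 1873 genes, 8 lists, 0.551 for activation and 0.279 for clearance, with 2, 4, 1 and 2 splits as large and 2939, 9, 0.521 and 0.310 as the highest others, and the split with 2939 genes is the one between many and few genes detected, which points to a structure of the samples other than genotype, and a term for those classes left 1021 genes.

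The genes that differed in the same direction at MII and PN3 may reflect a lack of Smarca4 in the growing oocyte or the background of the females. A passenger region beside Smarca4 is argued against as the whole cause: of 16 placed genes other than Smarca4, on 12 chromosomes, 1 lay on chromosome 9 (Aldh1a2, 71215789 to 71296243), where 0.891 were expected. Only chromosome 9 was counted, so linked regions elsewhere, such as one around the Cre driver, were not tested. Mfhas1 and Fgl1, both among these genes, lie on chromosome 8 (from 35587798 and from 41191434). A strain difference stays open, since 0 of the libraries have the strain of the female in their labels. At PN3 chance in the grouping of these libraries could be excluded for the 10 called genes, the deleted Smarca4 among them (1 of 35 splits, highest other 2). It could not be excluded for the lists (30 of 35 splits gave at least the 1 list, highest other 6). The split of PN3 replicates 1 and 2 from 3 and 4 was 1 of those with 6 lists, and with a term for it 9 genes were called.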

How the results depend on the processing

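Tests chosen after the results were seen were the fits of MII with PN3 and of E2C with L2C, leaving out both WT_E2C replicate 2 and WT_L2C replicate 3, a stage alone without a library, the terms for PN3 replicates and for L2C libraries with many genes detected (classes set from the data), lists from 1 genotype, the estimated correlation for the defined lists, TPM and each library left out for the fixed lists, leaving out both E2C replicates 3, and all for the cleared genes at E2C. No called named gene, called fixed list or defined list changed its sign (0 of 2148, 143 and 77 values). Many of these values could not turn. Fitting stages alone or together, other filters and an estimated correlation leave the log2 difference of a gene as it was. The replicate block does so too where WT and KO have the same replicate numbers. The balance of the calls at E2C did turn, from 100 higher and 112 lower to 153 and 81 with TPM, 137 and 94 with FPKM as deposited, and 113 and 66 with a pseudocount of 0.1, and at L2C the medians of 2-cell and proteasome genes differed in sign between libraries with many and few genes detected. The fixed lists were not run with another pseudocount, another filter or library weights. The counts depended strongly on how the spread was estimated, and also on single libraries. Libraries varied more at E2C and L2C than at MII and PN3. The simulated counts at MII, 182.4 with the shared spread and 200.6 alone, differed little, unlike the real 1 and 424. The simulated changes were 2-fold and 4-fold, while the calls with MII alone included smaller ones, such as -0.25 (log2) for Vrtn. The simulation therefore cannot decide how the 2 fits treat such changes. Depth is unknown, so its limits could not be computed. Of 127 named calls, those kept under every alternative were Smarca4 at MII, Dip2c, Sh2d3c and Smarca4 at PN3, 0 of 38 at E2C and 0 of 83 at L2C.

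With each stage fitted alone the counts were 424 at MII, 94 at PN3, 0 at E2C and 0 at L2C, and Smarca4 was called at 2 stages; with WT_E2C replicate 2 also left out E2C gave 0. With 2 stages fitted together MII gave 226, PN3 505, E2C 1 and L2C 0, the interactions gave 14, 1 and 0, and the WT change from MII to PN3 gave 4869. Library weights gave 1137 at MII, 666 at PN3, 24 at E2C, 3692 at L2C, interactions of 445, 10 and 1381, 5994 for WT MII to PN3 and 159 genes called in the same direction at successive stages, in place of 26. The cause was not tested beyond the simulated data on shared spread.

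With a pseudocount of 0.1 MII gave 2, the interaction from E2C to L2C 327 and the genes called at successive stages 17. Without a filter MII gave 14 and the interactions 5, 2 and 296, and a filter at an FPKM of 5 gave 5 at PN3. With TPM the interaction from E2C to L2C was 461 and the OXPHOS list at PN3 lost its call (adjusted p = 0.0583). With both named WT libraries left out L2C gave 5346 and the interactions 18 from PN3 to E2C and 3566 from E2C to L2C. A term for many genes detected gave 1021 at L2C and a proteasome adjusted p of 0.0610. With it the 2-cell median was 0.19 (camera adjusted p = 0.0475, 2 called higher), and 20 oocyte and 4 Obox genes were called higher. Lower members were 12 for ribosome biogenesis, 2 for ribosomal proteins, 5 for spliceosome and 9 for Pol II. With both E2C replicates 3 left out E2C gave 1320 and the interactions 321 from PN3 to E2C and 1406 from E2C to L2C. With E2C and L2C fitted together 0 members of the lists called there were called, though the lists kept their calls. Gained lists were, with both E2C replicates 3 left out, the stress list (adjusted p = 0.00170) and spliceosome (0.0411) at E2C, with both named WT libraries left out Obox at E2C (0.0150), and with the term for many genes detected histones and the stress list at L2C (0.0475 each). The cause was not tested for these.

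With an estimated correlation 0 fixed lists were called in place of 11: adjusted p was 0.952 for OXPHOS at PN3, 0.594 and 0.679 for 2-cell genes and histones at E2C, and at L2C 0.695 for 2-cell genes, 0.285 for Obox, oocyte, ribosome biogenesis and spliceosome lists, 0.431 for ribosomal proteins and Pol II, and 0.582 for proteasome. The maternally cleared genes (median 0.28 at L2C, 0.27 at E2C) also lost their call, and the activation and early lists kept theirs.

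Leaving out 1 library gave 6 to 9 genes at PN3 (6 without KO_PN3 replicate 2, WT_PN3 replicate 2 or WT_PN3 replicate 3), 55 to 1514 at E2C and 346 to 4274 at L2C. Without WT_L2C replicate 3, 1850 of the 1873 genes were kept among 4274, and without WT_E2C replicate 2, 70 of the 212 among 120. It gave interactions of 0 to 261 from PN3 to E2C (261 without WT_E2C replicate 3) and 94 to 3180 from E2C to L2C, 790 to 1079 for WT MII to PN3 (790, 824 and 842 without WT_MII replicates 2, 1 and 3) and 11 (without KO_E2C replicate 2) to 138 (without WT_E2C replicate 3) genes called at successive stages. Adjusted p ranged from 3.47e-04 to 0.392 for OXPHOS at PN3, 7.95e-08 to 0.109 for 2-cell genes at L2C, 5.97e-04 to 0.238 for proteasome and 0.00855 to 0.138 for Pol II. Of 26 lists with called members but no call of the list at E2C or L2C, the count of members moved by over 1.5 times in 26.

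The replicate numbers were not taken to pair the samples, because at no stage did every same-number pair have a correlation of deviations over 0.1 (6 of 12 pairs did, with a range of -0.20 to 0.46). As a hint from the data and not the design, the WT libraries closest to the KO library of their own number were 3 of 3 at E2C, 3 of 4 at PN3, 1 of 2 at MII and 1 of 3 at L2C, so a shared origin stays open. WT_MII replicate 3 has no KO library of its number. The deviations of the 2 KO libraries at MII mirror each other, so MII says little on pairing. With the replicate block the counts were 1, 7, 168 and 1983 from MII to L2C and 825 for the interaction from E2C to L2C, 12 lists were called in place of 11, with histones at PN3 gained (adjusted p = 0.0486). No total over all genes moved by over 1.5 times, but the called 2-cell genes at L2C went from 6 to 12 and the histones at E2C from 4 to 2.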

Other observations

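The regrouping tests here were chosen after the results were seen. The WT stage changes were planned comparisons. Ribosomal protein and respiratory chain genes fell from MII to PN3: 45 of 85 cytosolic ribosomal protein genes fell in WT with a median of -0.99, and 34 of 77 OXPHOS genes fell and 1 rose with a median of -0.84. From PN3 to E2C 53 of 92 ribosome biogenesis genes fell and 10 rose (median -0.65) and 24 of 44 proteasome genes fell and 6 rose (median -0.70), and 38 of 77 OXPHOS genes fell and 4 rose (median -0.87). From E2C to L2C ribosomal protein genes rose by a median of 2.69 in WT and 2.01 in KO, and ribosome biogenesis genes by 2.23 and 1.52, where with an estimated correlation the adjusted p was 0.287 for both in WT, and 0.5 and 0.512 in KO. Of the OXPHOS genes 40 rose and 7 fell in WT (median 0.95), and the list was not called (adjusted p = 0.204). Camera called the falls (adjusted p = 3.69e-23, 1.73e-15, 5.94e-06, 7.68e-04 and 6.39e-05 in that order), and with an estimated correlation the adjusted p was 0.144, 0.0593, 0.613, 0.613 and 0.448.

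The watch genes Dux, Zfp352 and Zscan4d rose in both genotypes up to E2C. Of these, only Zscan4d had a KO effect called as different between E2C and L2C (limma adjusted p = 0.0393). From PN3 to E2C Dux rose by 1.49 in WT and 2.08 in KO, Zfp352 by 4.52 and 4.23, and Zscan4d by 3.93 and 2.79 (limma adjusted p of at most 7.02e-05). From E2C to L2C Obox3 rose by 2.95 and 3.59, and Dux fell by 3.03 in WT and fell by 2.69 in KO. Zfp352 changed by -0.11 in WT (limma adjusted p = 0.808) and rose by 1.64 in KO (limma adjusted p = 8.33e-04). Zscan4d fell by 2.06 in WT, while its KO change of 0.36 did not pass the test (adjusted p = 0.544). At L2C it stood at 4.32, 4.73 and 33.4 in WT and 14.7, 22.2 and 23.3 in KO. WT_L2C replicate 3 thus showed no fall from the WT range at E2C (32.7 to 52.4) and lay above every KO library.

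For 18 genes, KO libraries lay all above or all below WT libraries in the same direction at all 4 stages, 10 higher and 8 lower, a count that does not use the estimate of spread. Chance in the grouping of these libraries could be excluded: 1 of 100 drawn regroupings within the stages, the real one, gave as many, and the highest other gave 1. A chance difference between females is not covered, since no label says whether replicates came from separate females. Besides Smarca4 they include Cttnbp2 (0.89, 0.63, 1.18 and 1.35 from MII to L2C), Aldh1a2 (0.71, 0.81, 0.97 and 1.10), Zmynd11 (0.49, 0.70, 0.73 and 0.82), Dip2c (-0.82, -0.86, -0.86 and -0.76) and Runx2 (-0.49, -0.60, -0.51 and -0.80). Of these, Aldh1a2 and Runx2 were named after their values were seen. Zmynd11 and Dip2c lie close together on chromosome 13, so they may not be separate effects. The strain of the females stays open for these genes as well.

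For the WT stage changes chance in the grouping of these libraries could be excluded from MII to PN3 (1 of 35 splits gave the 1342 genes, highest other 313) and from PN3 to E2C (1 of 35 gave the 4942 genes, highest other 2358). From E2C to L2C 10 splits allow no share under 0.05. The real value was 7900, with 1 split as large and a highest other of 1810.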
